A study of Homo sapiens with 12 samples.

How the data were processed

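RNA from 2 human B cell lymphoma lines was sequenced, WSU-DLCL2 (control, 5 and 50 nM CUDC-907) and DOHH-2 (control, 2 and 20 nM), each after 6 h and 12 h, which gave 12 libraries with 1 library per condition. Libraries were made from total RNA with the TruSeq RNA kit per the labels, and the labels do not state what the control cells received. The deposited file holds read counts per gene and library, whole numbers without normalization. The submitters' processing notes name STAR 2.4.0j, featureCounts 1.4.6, edgeR 3.8.5 and the hg19 genome without saying which step each served. The gene annotation and the strand setting are not given in the sources used here. The file lists 55765 genes, and 28 of its names, 26 of them distinct, are dates made from gene symbols by a spreadsheet; these were kept as they stand and none is named.

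Library totals ran from 27574463 to 36682390 counts. A gene with counts in both controls of a line can be set against a count of 0 in another group down to a floor of 3 counts, and no fold is given where both groups are at or below that floor. Where the controls of a line held 0 counts, a fold is a lower bound against 3 counts over both controls, and with 1 to 3 counts it is a ratio with its exact 95% counting interval. The controls of a line at 6 h and 12 h differed by more than counting error, with a chi-square of 42.1 per gene in WSU-DLCL2 and 20.1 in DOHH-2.

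Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were filtered with filterByExpr by line and dose level (minimum count 10), which kept 18167 genes with 99.9% of all counts, and libraries were scaled with TMM factors. A quasi-likelihood model held 1 term for each of the 4 sets of line and time plus the effects of the lower and the higher dose within each line, which leaves 4 residual degrees of freedom. The spread it measures is that of a dose effect between the 6 h and 12 h sets of a line, so a real change with time adds to it. The prior degrees of freedom were 10.5 and the biological coefficient of variation 0.152. Differences between times came from a second fit with dose by time terms shared by both lines and 2 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. A difference between lines or times was called only by its own test.

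Before the data were examined, 32 gene lists, the comparisons, the tests, most alternatives and the rule for named genes were fixed. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, and with fry, which tests whether the genes of a list move on balance one way, with adjustment over the lists of a comparison. Counts of list members are given over all genes tested and adjusted over the list alone. With an estimated correlation no list passed in any comparison that the text reports. The rule named MYC in every library first. For each line at the higher dose it then named the 10 genes with the largest rise and the 10 with the largest fall among those that passed, had the same sign at both times and doses and had a mean of at least 5 CPM. For the mean of both lines and for the differences between lines and times it named the 5 largest each way, and from each list described up to 4 members with the largest absolute change past the threshold. Some genes that the rule names are not reported here. Genes singled out otherwise are said to have been chosen after their values were seen.

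The pipeline was tested on simulated data in which genes of known fold were added to counts of the same depth. Their spread followed the trend of the data with expression level, without spread particular to a gene and without an effect of time. Genes were drawn independently, and only 67, 67 and 66 of them were changed at the 3 folds. Far more genes changed in the data, so recovery and false calls there can differ from these values. At a fold of 1.5, 2 and 4, edgeR recovered 14.9%, 55.2% and 77.3% of the changed genes at 50 nM in WSU-DLCL2 with 5 false calls among 18167 genes, and 10.4%, 46.3% and 83.3% at 20 nM in DOHH-2 with 6 false calls. Recovery was 8.96%, 41.8% and 65.2% at 5 nM in WSU-DLCL2, and 4.48%, 38.8% and 68.2% at 2 nM in DOHH-2. For the mean of both lines it was 31.3%, 61.2% and 86.4%, for the difference between lines 2.99%, 14.9% and 47% and for the difference between times 0%, 26.9% and 63.6%.

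Alternatives were RLE factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at a mean of 5 CPM, each line fitted alone, a dose effect shared by both lines, a fold of at least 2 and leaving out each set of line and time in turn. Upper quartile factors and the removal of mitochondrial genes were added after seeing the data. Single library pairs were given as log2 ratios of CPM with a prior count of 2 and no test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.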

Results

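RNA was sequenced from 2 B cell lymphoma lines, WSU-DLCL2 and DOHH-2, grown with CUDC-907, an inhibitor of both PI3-kinase and histone deacetylases, or kept as controls. WSU-DLCL2 cells received 5 or 50 nM and DOHH-2 cells 2 or 20 nM, and each line was collected at 6 h and 12 h. Each of the 12 conditions had 1 library by its label, so no condition was replicated. The p-values of dose effects rest on their spread between the 6 h and 12 h sets, and those of differences between times on how far the lines disagree. Counting intervals and floors cover counting error only. Total counts in WSU-DLCL2 for control, 5 and 50 nM were 32480372, 32841240 and 34048308 at 6 h and 36081848, 36682390 and 34756749 at 12 h. In DOHH-2 the totals for control, 2 and 20 nM were 32682966, 28748525 and 27574463 at 6 h and 33637269, 35453416 and 28078538 at 12 h. A total of 18167 genes had enough counts to be tested. Levels are in CPM (counts scaled by the TMM-adjusted library total), changes are fitted log2 fold changes, and the value after ± is the standard error. The comparisons ask which genes were differentially regulated by the drug in each line, at each dose, and between lines and times.

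MYC, the transcription factor that drives growth and ribosome production in many B cell lymphomas, was lower than the control of the same line and time in 8 of 8 treated libraries. In WSU-DLCL2 the MYC level went from 382 CPM in the 6 h control to 139 CPM at 5 nM and 76.8 CPM at 50 nM, and from 367 to 197 and 78.4 CPM at 12 h. In DOHH-2 it went from 375 to 166 CPM at 2 nM and 33.2 CPM at 20 nM at 6 h, and from 391 to 294 and 120 CPM at 12 h. MYC fell by 2.27 ± 0.30 on the log2 scale at 50 nM (adjusted p = 2.55e-05) and by 1.17 ± 0.29 at 5 nM in WSU-DLCL2. It fell by 2.58 ± 0.31 at 20 nM in DOHH-2 (adjusted p = 2.52e-05), while the value of -0.85 ± 0.29 at 2 nM did not pass the threshold.

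**Figure D1:**
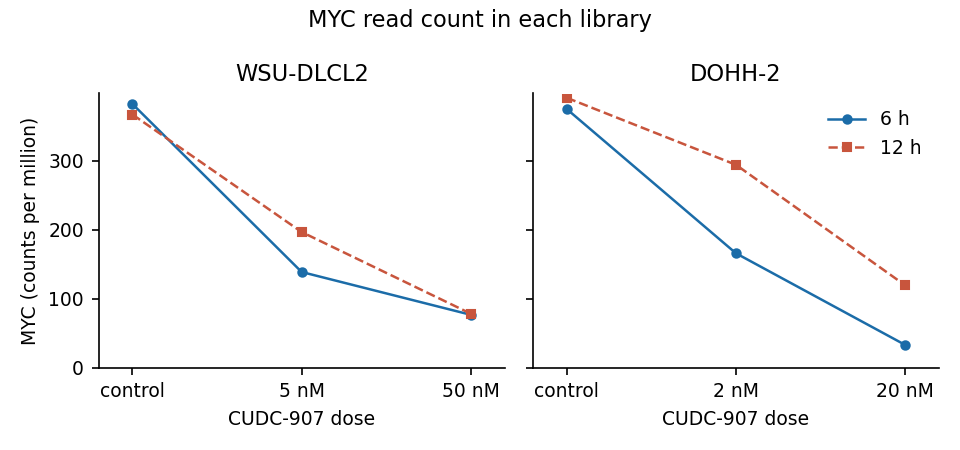
MYC level in CPM (vertical axis, from 0) against CUDC-907 dose in nM for each cell line, with 1 point per library and 1 line per collection time. MYC lay between 367 and 391 CPM in the 4 controls and between 33.2 and 120 CPM in the 4 libraries at the higher dose.

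In WSU-DLCL2 at 50 nM, the kinase inhibitor genes CDKN1A and CDKN2B and genes known to respond to deacetylase inhibition rose, while ribosome assembly and B cell identity genes fell. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, went from 2.76 to 89.5 CPM at 6 h and from 1.75 to 119 CPM at 12 h (log2 fold change 5.56 ± 0.29). H1F0, a linker histone gene, went from 4.85 to 484 CPM at 6 h and from 5.15 to 493 CPM at 12 h (6.61 ± 0.29). CDKN2B, the gene of another kinase inhibitor, rose by 5.10 ± 0.32. TNFRSF17, the gene of the plasma cell receptor BCMA, fell by 3.70 ± 0.37 on the log2 scale.

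Among 35 MYC targets of ribosome biogenesis, 30 fell, 1 rose and 4 did not pass the test at 50 nM in WSU-DLCL2 (30 and 1 adjusted over the list alone). WDR74 was at -1.66 ± 0.18, MRTO4 at -1.64 ± 0.20 and MYBBP1A at -1.63 ± 0.20. The list was lower than other genes by camera with a preset correlation (adjusted p = 2e-09), but not with an estimated one (adjusted p = 0.744 with an estimated correlation). Of 29 MYC targets of metabolism 21 fell and 1 rose (22 and 1 adjusted over the list alone, camera adjusted p = 2.09e-05; adjusted p = 0.744 with an estimated correlation). The folate carrier SLC19A1 was at -1.73 ± 0.21 and the spermidine synthase SRM at -1.41 ± 0.22, whereas the cyclin gene CCND2 rose by 4.58 ± 0.52. None of 56 genes of cytosolic ribosomal proteins passed the test in either line (edgeR; adjusted over the list alone also 0). Their median log2 fold change was -0.13 at 50 nM in WSU-DLCL2 and 0.11 at 20 nM in DOHH-2. In the MYC network itself, MYCL rose by 3.60 ± 0.31, MXD1 by 1.93 ± 0.26 and MXI1 by 1.63 ± 0.19, and 4 of 11 members rose and 4 fell (4 and 4 adjusted over the list alone).

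Of 16 genes known to be induced by deacetylase inhibitors, 11 rose, 0 fell and 5 did not pass in WSU-DLCL2 at 50 nM (12 and 0 adjusted over the list alone, camera adjusted p = 1.16e-04; adjusted p = 0.744 with an estimated correlation). CRIP2 had 3 counts in both controls together and 2174 at 50 nM, a ratio of 630 with a counting interval of 215 to 3056, and DHRS2 rose by 5.46 ± 0.70. FOXO targets, a group held down by PI3-kinase signalling, had 18 of 24 members higher and 2 lower (18 and 3 adjusted over the list alone, camera adjusted p = 1.16e-04; adjusted p = 0.744 with an estimated correlation). The insulin receptor gene INSR rose by 4.06 ± 0.25 and KLF2 by 5.02 ± 0.54, and S1PR1, with 0 control counts, was at least 13.3-fold higher against a floor of 3 counts over both controls. Of 11 histone deacetylase genes 5 rose and 3 fell (5 and 3 adjusted over the list alone). HDAC11 was at 3.41 ± 0.39 and HDAC7 at -1.84 ± 0.23, and HDAC5 rose as well. Of 21 PI3K and AKT pathway genes 4 rose and 5 fell (4 and 5 adjusted over the list alone). The phosphatase gene INPP5D was at -1.44 ± 0.20.

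B cell genes fell at 50 nM in WSU-DLCL2. Of 24 genes of germinal centre B cell identity 18 fell and 2 rose (18 and 2 adjusted over the list alone, camera adjusted p = 2.09e-05; adjusted p = 0.744 with an estimated correlation). IKZF3 was at -2.62 ± 0.31, S1PR2 at -2.45 ± 0.30 and RGS13 at -2.44 ± 0.26. Of 23 genes of B cell receptor signalling 15 fell and 2 rose (17 and 2 adjusted over the list alone, camera adjusted p = 6.68e-05; adjusted p = 0.744 with an estimated correlation). The adaptor BLNK was at -2.35 ± 0.23, the phosphatase PTPN6 at -2.26 ± 0.16 and the kinase PRKCB at 3.52 ± 0.26. Plasma cell genes went both ways, 6 of 12 higher and 5 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.602). PRDM1, the regulator of plasma cell formation, was at 3.52 ± 0.63, SDC1 at 3.50 ± 0.40 and TNFRSF17 fell. The 10 largest falls chosen by the rule also held IGHG1 (-3.61 ± 0.43), IGHG4 (-3.22 ± 0.31), LRMP (-2.98 ± 0.29), NUGGC (-2.95 ± 0.33), KMO (-2.90 ± 0.29) and FERMT3 (-2.78 ± 0.23). Reads of immunoglobulin constant genes can be shared between their paralogs, so the values of IGHG1 and IGHG4 are not independent.

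Proliferation genes were lower as well. Of 28 DNA replication genes 10 fell and 0 rose at 50 nM in WSU-DLCL2 (10 and 0 adjusted over the list alone, camera adjusted p = 6.97e-04; adjusted p = 0.76 with an estimated correlation). Thymidylate synthase TYMS was at -1.96 ± 0.19 and E2F2 at -1.27 ± 0.18. Of 25 G2/M genes 12 fell and 2 rose (14 and 2 adjusted over the list alone, camera adjusted p = 0.00502; adjusted p = 0.76 with an estimated correlation). PLK1 was at -1.35 ± 0.20 and CCNA2 at -1.35 ± 0.17. In cell death genes, the pro-apoptotic HRK rose by 3.79 ± 0.40 and BBC3 by 3.68 ± 0.34 while BID fell by 1.43 ± 0.20, with 5 of 10 members higher and 3 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.501). Of 9 anti-apoptotic genes 5 fell, among them BCL2 at -1.48 ± 0.28, and BIRC3 rose by 1.61 ± 0.23 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0682). Immediate early and ERK output genes were higher in 10 of 18 and lower in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0125; adjusted p = 0.76 with an estimated correlation). FOS was at 3.62 ± 0.34 and JUN at 3.11 ± 0.38. Without the WSU-DLCL2 12 h set the DNA replication list (camera adjusted p = 0.111) and the ERK output list (camera adjusted p = 0.128) did not pass.

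Of 20 p53 targets 10 rose and 3 fell at 50 nM in WSU-DLCL2 (10 and 4 adjusted over the list alone, camera adjusted p = 0.0778). TP53INP1 was at 3.21 ± 0.16. Interferon response genes rose in 6 of 20 and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.425). IFI6 was at 3.82 ± 0.41 and IRF7 at 1.86 ± 0.23. MHC class II genes rose in 5 of 12 and fell in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.425). HLA-DMA was at 1.08 ± 0.17 and HLA-DOB at -0.92 ± 0.21.

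Genes not usually expressed in B cells also rose at 50 nM in WSU-DLCL2. Of 12 neuronal genes 7 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0123; adjusted p = 0.744 with an estimated correlation). The synapsin gene SYN1 was at 6.25 ± 0.58, and NRXN2 had 1 control count against 774 at 50 nM, a ratio of 673 with a counting interval of 120 to 26602. CHGB of this list had 1 control count and DPYSL3 2. Further members of the list had too few counts to be tested. Members near 0 in the controls were tested because other libraries held counts of them, which favours genes that rise. Without the WSU-DLCL2 12 h set the neuronal list did not pass (camera adjusted p = 0.111). Among the largest rises chosen by the rule, CGREF1 and ATP1B2 had 1 control count each, with ratios of 1293 (232 to 51110) and 1285 (230 to 50801), and PTRF, a gene of caveolae, rose by 8.81 ± 0.40. Some markers of other cell types changed too: 3 T cell markers rose and 1 fell of 5 tested, 1 myeloid marker rose of 7, and 2 epithelial and stromal markers rose and 1 fell of 3 (the same counts adjusted over the list alone). Each of these lists has 10 members, and the others had too few counts to be tested. The T cell marker CD3E was at 2.90 ± 0.49, and the collagen gene COL1A1 had 1 control count and 655 at 50 nM.

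In all, 8008 of 18167 genes passed the edgeR test at 50 nM in WSU-DLCL2, 4526 higher and 3482 lower, and 4858 of them changed at least 2-fold. Without the 12 h set 3741 genes passed, and among genes with a mean of at least 5 CPM 4946 passed. With upper quartile factors, chosen after seeing the data, the median of all genes moved from 0.05 to 0.22 and 67.8% of the changed genes were higher, against 56.5% with TMM factors and 53.2% among genes of at least 5 CPM.

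At 5 nM in WSU-DLCL2 the MYC targets fell about as widely as at 50 nM, while B cell identity genes did not fall as a group. CDKN1A rose by 4.88 ± 0.28 and H1F0 by 4.72 ± 0.27. Of 35 MYC targets of ribosome biogenesis 30 fell and 0 rose (33 and 0 adjusted over the list alone, camera adjusted p = 2e-13; adjusted p = 0.536 with an estimated correlation). MYBBP1A was at -1.52 ± 0.20 and NOP16 at -1.48 ± 0.25. FOXO targets rose in 14 of 24 and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 2.34e-04; adjusted p = 0.536 with an estimated correlation). DNA replication genes fell in 10 of 28 and rose in 0 (13 and 0 adjusted over the list alone, camera adjusted p = 2.21e-06; adjusted p = 0.536 with an estimated correlation). TYMS was at -0.89 ± 0.19.

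Of 24 germinal centre identity genes, 5 fell and 4 rose at 5 nM in WSU-DLCL2 (5 and 5 adjusted over the list alone, camera adjusted p = 0.247). FOXP1 was at 1.37 ± 0.25 and LMO2 at -0.80 ± 0.20. MHC class II genes, which present antigen to T cells, rose in 8 of 12 and fell in 0 (10 and 0 adjusted over the list alone, camera adjusted p = 0.00419; adjusted p = 0.63 with an estimated correlation). HLA-DQB1 was at 1.22 ± 0.18 and HLA-DMA at 1.14 ± 0.17. Interferon response genes rose in 9 of 20 and fell in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 0.0206; adjusted p = 0.63 with an estimated correlation). IFI6 was at 3.02 ± 0.41, and EPSTI1 also rose. Of 7 myeloid markers 4 rose at 5 nM (4 adjusted over the list alone), among them LYZ at 2.59 ± 0.58. The level of LYZ was low, at 0 CPM in the 6 h control and 0.205 CPM in the 12 h control. At 5 nM it was 0.146 CPM at 6 h and 1.13 CPM at 12 h. Markers near 0 in the controls were tested because other libraries held counts of them, which favours genes that rise. In the direct test of 50 nM against 5 nM, 19 of 24 germinal centre genes were lower and 0 higher (21 and 0 adjusted over the list alone, camera adjusted p = 1.07e-08; adjusted p = 0.561 with an estimated correlation), and 14 of 23 B cell receptor signalling genes were lower and 0 higher (17 and 0 adjusted over the list alone, camera adjusted p = 2.63e-06; adjusted p = 0.578 with an estimated correlation). MYC targets of ribosome biogenesis had 1 member higher and 2 lower between those doses (0 and 1 adjusted over the list alone, camera adjusted p = 0.483).

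At 5 nM 5263 genes changed in WSU-DLCL2, 3634 higher and 1629 lower, and 3283 changed at least 2-fold. Between 50 and 5 nM 3531 genes differed, 1581 higher and 1950 lower at 50 nM, against 1796 and 1703 without mitochondrial genes. The count at 5 nM was 2674 without the 6 h set, 1804 without the 12 h set and 2203 among genes of at least 5 CPM, with 85.3% higher under upper quartile factors and 59.6% without mitochondrial genes, against 69.0%. The count between doses was 1492 without the 6 h set and 0 without the 12 h set. That loss does not show the 6 h libraries to be alike at both doses, since the median of the germinal centre list against the control was -0.29 at 5 nM and -1.17 at 50 nM at 6 h, and 0.07 and -1.25 at 12 h.

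In DOHH-2 at 20 nM the same MYC target and B cell lists fell, and interferon response genes rose as a group. KLF2, a transcription factor gene under FOXO control, had 3 control counts and 126 at 20 nM, a ratio of 46.7 with a counting interval of 15.6 to 230. The metallothionein gene MT2A rose by 3.55 ± 0.31 and the autophagy gene GABARAPL1 by 3.28 ± 0.24. The transcription factor gene TFAP4, itself a MYC target, fell by 2.61 ± 0.27 on the log2 scale, and TNFRSF17 fell by 2.51 ± 0.36.

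Of 35 MYC targets of ribosome biogenesis, 31 fell and 1 rose at 20 nM in DOHH-2 (31 and 1 adjusted over the list alone, camera adjusted p = 1.56e-13; adjusted p = 0.705 with an estimated correlation). MYBBP1A was at -1.84 ± 0.20 and NOP16 at -1.74 ± 0.25. MYC targets of metabolism fell in 21 of 29 and rose in 0 (24 and 0 adjusted over the list alone, camera adjusted p = 9.66e-09; adjusted p = 0.705 with an estimated correlation). SRM was at -1.65 ± 0.22, and SLC19A1 fell here too. Fatty acid synthesis genes fell in 6 of 9 and rose in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00423; adjusted p = 0.705 with an estimated correlation). FASN was at -1.58 ± 0.22 and FADS2 at -1.46 ± 0.16. DNA replication genes fell in 12 of 28 and rose in 0 (14 and 0 adjusted over the list alone, camera adjusted p = 4.22e-06; adjusted p = 0.705 with an estimated correlation). TYMS was at -1.61 ± 0.19 and E2F2 at -1.56 ± 0.18. G2/M genes fell in 11 of 25 and rose in 2 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00383; adjusted p = 0.705 with an estimated correlation). UBE2C was at -1.15 ± 0.19. ATF4 and stress response genes fell in 12 of 19 and rose in 1 (13 and 2 adjusted over the list alone, camera adjusted p = 3.99e-04; adjusted p = 0.47 with an estimated correlation). ATF5 was at -1.94 ± 0.17 and TRIB3 at -1.40 ± 0.17. Fatty acid synthesis genes did not pass without the DOHH-2 12 h set (camera adjusted p = 0.0783), and G2/M genes did not without the 6 h set (camera adjusted p = 0.276).

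Germinal centre identity genes fell in 14 of 24 and rose in 1 at 20 nM in DOHH-2 (15 and 1 adjusted over the list alone, camera adjusted p = 5.28e-04; adjusted p = 0.705 with an estimated correlation). IKZF3 was at -2.31 ± 0.31 and S1PR2 at -1.99 ± 0.30. B cell receptor signalling genes fell in 13 of 23 and rose in 4 (13 and 6 adjusted over the list alone, camera adjusted p = 0.00882; adjusted p = 0.705 with an estimated correlation). The receptor subunit CD79A was at -1.96 ± 0.23 and the scaffold BANK1 at 3.13 ± 0.37. FOXO targets rose in 17 of 24 and fell in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 0.00739; adjusted p = 0.705 with an estimated correlation). SESN3 was at 2.05 ± 0.17. Genes induced by deacetylase inhibitors rose in 9 of 16 and fell in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0322; adjusted p = 0.705 with an estimated correlation). DHRS2 was at 5.80 ± 0.71. Without the DOHH-2 12 h set, FOXO targets (camera adjusted p = 0.0762) and genes induced by deacetylase inhibitors (camera adjusted p = 0.117) did not pass. B cell receptor signalling genes did not pass without the 6 h set (camera adjusted p = 0.0506). In the histone deacetylase list 4 of 11 rose and 1 fell (4 and 1 adjusted over the list alone). HDAC11 was at 3.21 ± 0.43 and HDAC7 at -1.96 ± 0.24.

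Interferon response genes rose in 15 of 20 and fell in 0 at 20 nM in DOHH-2 (15 and 0 adjusted over the list alone, camera adjusted p = 5.28e-04; adjusted p = 0.705 with an estimated correlation). IFIT1 was at 5.01 ± 0.71, IFIT3 at 4.06 ± 0.45 and IFI6 at 3.83 ± 0.36. MHC class II genes rose in 9 of 12 and fell in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 0.016; adjusted p = 0.705 with an estimated correlation). HLA-DQA1 was at 1.51 ± 0.18 and HLA-DRB1 at 1.39 ± 0.15. Without the DOHH-2 12 h set interferon response genes passed (camera adjusted p = 0.0042) and MHC class II genes did not (camera adjusted p = 0.09). In MHC class I presentation, 6 of 14 genes rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.324). The proteasome subunit PSMB9 was at 3.50 ± 0.22 and the peptide transporter TAP1 at 1.73 ± 0.19. NF-kB targets rose in 10 of 21 and fell in 3 (11 and 5 adjusted over the list alone, camera adjusted p = 0.324). TNFAIP3 was at 4.19 ± 0.40. ERK output genes rose in 10 of 18 and fell in 3 (10 and 4 adjusted over the list alone, camera adjusted p = 0.218), with EGR2 at 5.89 ± 0.53 and DUSP5 at 5.59 ± 0.38. Of the other-cell markers with enough counts to be tested, 3 of 5 T cell markers rose and 1 fell, and 3 of 7 myeloid and 2 of 3 epithelial and stromal markers rose with 0 lower (the same counts adjusted over the list alone). LYZ was at 1.62 ± 0.32, and COL1A1, at 0 control counts, was at least 132-fold higher. At 20 nM 6595 genes changed, 4063 higher and 2532 lower, and 3826 changed at least 2-fold. The count was 4379 without the 6 h set and 4086 without the 12 h set.

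**Figure D2:**
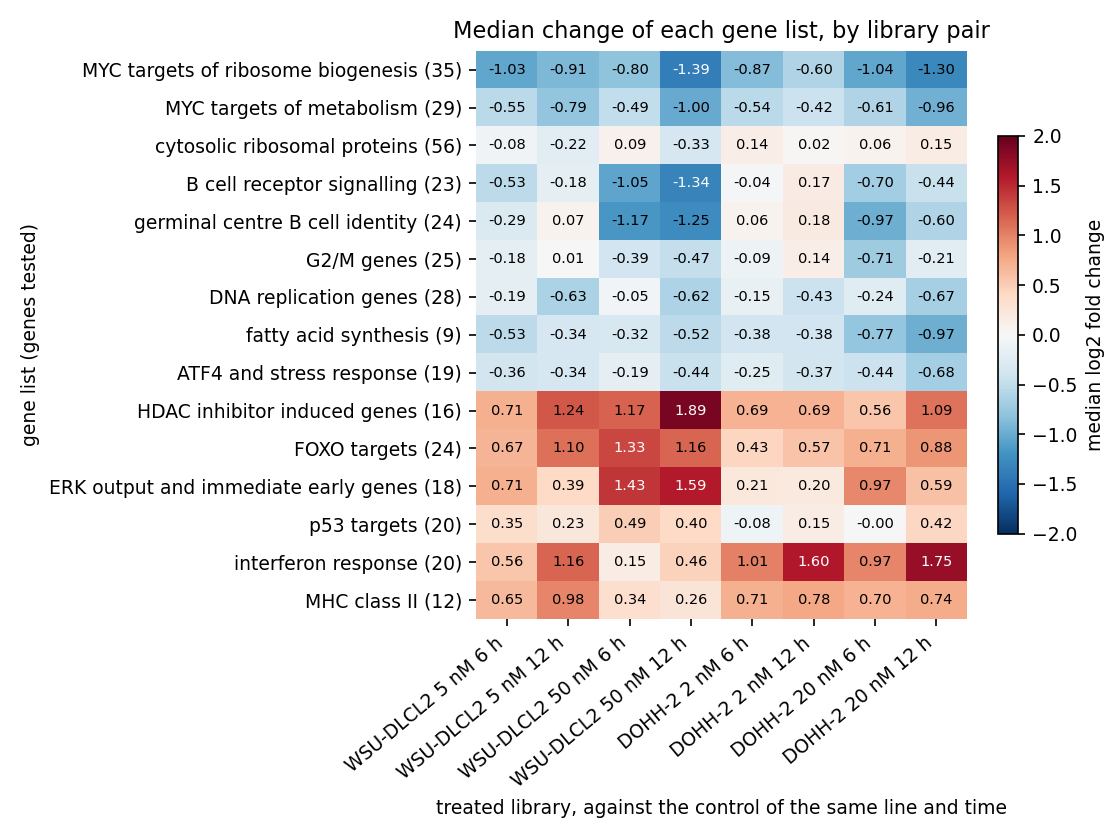
Median log2 ratio of the members of each gene list (colour) in each treated library against the control library of the same line and time, with lists in rows and the 8 library pairs in columns. MYC targets of ribosome biogenesis were below 0 in 8 of 8 pairs, from -0.60 to -1.39.

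At 2 nM in DOHH-2 MYC target genes fell and interferon and antigen presentation genes rose, while no gene of the germinal centre list fell. Of 35 MYC targets of ribosome biogenesis 23 fell and 0 rose (30 and 0 adjusted over the list alone, camera adjusted p = 3.03e-15; adjusted p = 0.5 with an estimated correlation). MYBBP1A was at -1.22 ± 0.19. Interferon response genes rose in 11 of 20 and fell in 0 (12 and 0 adjusted over the list alone, camera adjusted p = 9.65e-04; adjusted p = 0.5 with an estimated correlation). MX1 was at 3.12 ± 0.71 and IFIT3 at 2.37 ± 0.48. MHC class II genes rose in 9 of 12 and fell in 0 (10 and 0 adjusted over the list alone, camera adjusted p = 1.2e-04; adjusted p = 0.5 with an estimated correlation). HLA-DQA1 was at 1.71 ± 0.18. Germinal centre genes rose in 4 of 24 and fell in 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.816). LMO2 was at 0.86 ± 0.20. T cell markers rose in 3 of 5 and fell in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0389; adjusted p = 0.5 with an estimated correlation). CD3E was at 1.48 ± 0.30. Epithelial and stromal markers rose in 3 of the 3 tested (3 adjusted over the list alone, camera adjusted p = 0.0389; adjusted p = 0.5 with an estimated correlation). Among these epithelial and stromal markers, COL1A1 had 0 counts and PDGFRB 1 count in the DOHH-2 controls together. Such genes were tested only because other libraries held counts of them, which favours genes that rise. Myeloid markers rose in 3 of 7 and fell in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.249). Between 20 and 2 nM, 14 of 24 germinal centre genes were lower and 0 higher (15 and 0 adjusted over the list alone, camera adjusted p = 4.56e-07; adjusted p = 0.732 with an estimated correlation), and 12 of 23 B cell receptor signalling genes were lower and 1 higher (14 and 1 adjusted over the list alone, camera adjusted p = 3.09e-04; adjusted p = 0.732 with an estimated correlation).

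At 2 nM 2615 genes changed in DOHH-2, 2067 higher and 548 lower, and 2925 differed between 20 and 2 nM, 1527 higher and 1398 lower at 20 nM (1217 and 1400 by limma-voom). The count at 2 nM was 657 without the 6 h set, 787 without the 12 h set and 1220 among genes of at least 5 CPM, with 63.8% higher by DESeq2 and 61.9% without a filter on low counts, against 79.0%. The count between doses was 656 without the 6 h set and 1848 without the 12 h set.

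A set of genes was highest at the lower dose in both lines. Chosen after its values were seen, the group holds 71 genes that were higher at the lower dose than in the control and lower at the higher dose than at the lower one, in both lines. No fixed list held more than 2 of them. The Fc receptor-like gene FCRL2 went from 8.90 CPM in the WSU-DLCL2 6 h control to 26.1 at 5 nM and 8.50 at 50 nM, and from 14.2 to 33.9 and 6.65 CPM at 12 h. In DOHH-2 it went from 7.15 to 30.6 and 8.43 CPM at 6 h and from 7.45 to 39.7 and 15.0 CPM at 12 h. CD84, an adhesion receptor of B and T cells, was at 1.69 ± 0.25 at 5 nM and -0.84 ± 0.26 at 50 nM in WSU-DLCL2. FCGR2B (the inhibitory Fc receptor), TLR4, TNFSF8, FCRL3 and MS4A7 belonged to the group, as did the interferon-induced OAS2 and OAS3. In WSU-DLCL2 521 genes had this shape and in DOHH-2 198, against an overlap of 5.68 genes if the lines were independent, and 51 of the 71 were not higher than the control at the higher dose in either line. The opposite shape, lowest at the lower dose, was found for 41 and 4 genes with 0 shared. Under other scalings it was found for 11 to 30 genes in WSU-DLCL2 and 4 to 7 in DOHH-2. Both tests behind this shape use the lower-dose libraries of the line, and genes are not independent replicates. The value of 5.68 leaves out that the rise at the lower dose was itself shared by the lines.

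**Figure D3:**
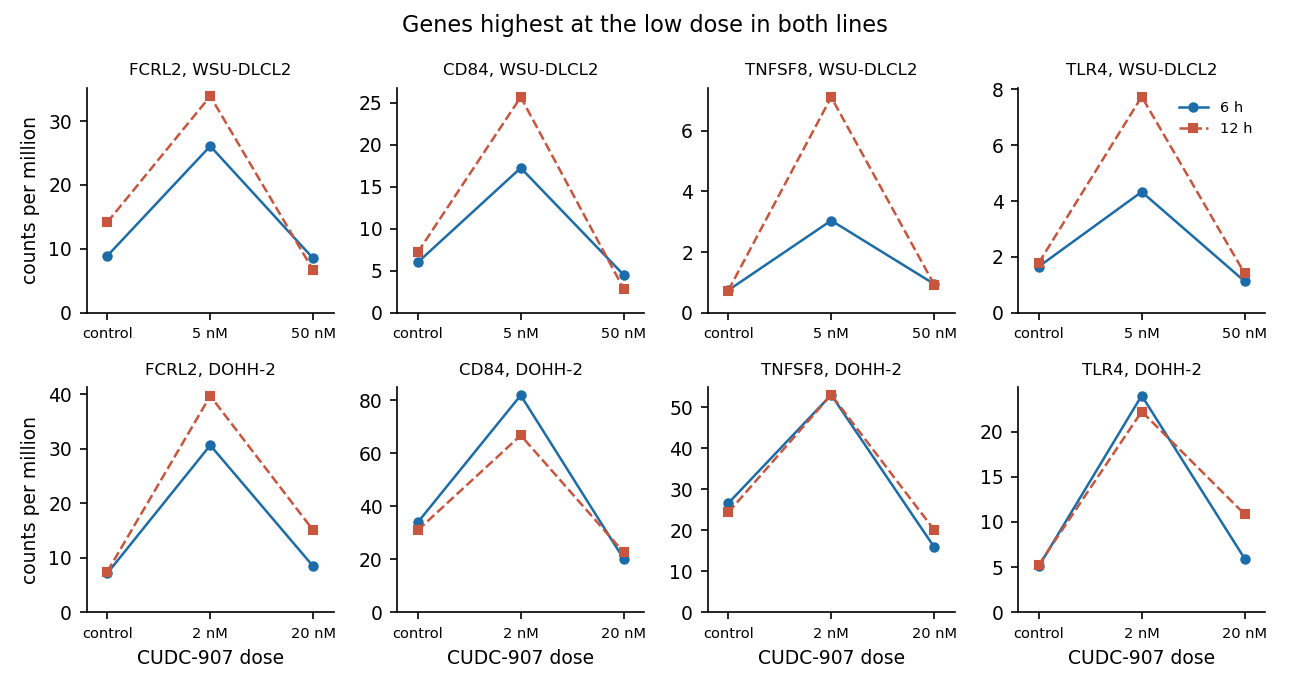
Level in CPM (vertical axes, each from 0) of FCRL2, CD84, TNFSF8 and TLR4 against CUDC-907 dose, with 1 panel per gene and cell line, 1 point per library and 1 line per collection time. FCRL2 rose from 7.45 CPM in the DOHH-2 12 h control to 39.7 CPM at 2 nM and stood at 15.0 CPM at 20 nM.

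Across genes, the high-dose changes of the lines went largely the same way (Pearson r = 0.62, Spearman rho = 0.69 over genes, which are not independent replicates). A total of 2617 genes were higher in both lines and 1943 lower in both, against 1012 and 485 if the lines were independent, and 118 went opposite ways. By the mean of both lines 9434 genes changed, 5519 higher and 3915 lower. FAM46C, a gene of an RNA polymerase that adds poly(A) tails, rose by 6.50 ± 0.28, and NRXN2 and CRIP2 were among the 5 largest rises. TNFRSF17 fell by 3.11 ± 0.26 on the log2 scale, CLEC2D by 2.82 ± 0.29 and NUGGC by 2.67 ± 0.23. MYC targets of ribosome biogenesis fell in 34 of 35 and rose in 1 (34 and 1 adjusted over the list alone, camera adjusted p = 4.01e-12; adjusted p = 0.635 with an estimated correlation). At a mean of at least 5 CPM the count was 6161, and 4505 genes changed at least 2-fold.

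**Figure D4:**
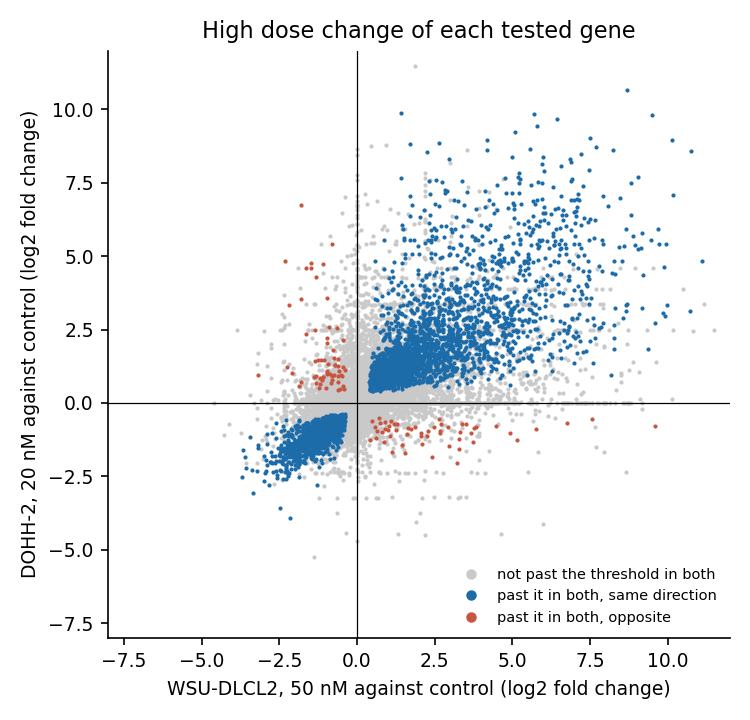
Log2 fold change at the higher dose in DOHH-2 (20 nM, vertical axis) against that in WSU-DLCL2 (50 nM, horizontal axis) with 1 point per tested gene. Blue points are the 2617 genes higher and the 1943 lower in both lines, red points the 118 that passed in opposite directions, and grey points all others.

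The lines were also compared directly at their higher doses, which differ (50 nM in WSU-DLCL2 and 20 nM in DOHH-2), so the line and the dose cannot be separated. CDKN1A rose more in WSU-DLCL2 (difference 4.04 ± 0.35, adjusted p = 1.16e-05), from a control level of 2.76 CPM at 6 h against 51.1 CPM in DOHH-2. Of 20 p53 targets 5 rose more in WSU-DLCL2 and 0 less (5 and 0 adjusted over the list alone, camera adjusted p = 0.00293; adjusted p = 0.47 with an estimated correlation; fry adjusted p = 0.0062). BBC3 differed by 3.12 ± 0.42, SESN1 by 1.98 ± 0.25 and the death receptor gene TNFRSF10B by 1.66 ± 0.27. The median of the p53 list was 0.49 in WSU-DLCL2 and -0.0026 in DOHH-2 at 6 h, and 0.40 and 0.42 at 12 h. Of 20 interferon response genes 5 were lower in WSU-DLCL2 relative to DOHH-2 and 0 higher (6 and 0 adjusted over the list alone). The list had camera adjusted p = 0.0136, or 0.788 with an estimated correlation, and did not pass by fry (adjusted p = 0.172). IFIT3 differed by -3.82 ± 0.83 and OAS1 by -1.67 ± 0.30. The number of differing interferon genes was 0 without the WSU-DLCL2 12 h set, and 1 without its 6 h set or without the DOHH-2 12 h set. FOXO targets differed in 3 of 24, all higher in WSU-DLCL2 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0196; adjusted p = 0.588 with an estimated correlation). INSR differed by 2.86 ± 0.31.

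The germinal centre regulator LMO2 fell by 2.08 ± 0.20 on the log2 scale in WSU-DLCL2 and was at 0.43 ± 0.20 in DOHH-2 (difference -2.51 ± 0.28). PTPN6 differed by -2.15 ± 0.23, with -2.26 ± 0.16 in WSU-DLCL2 and -0.11 ± 0.16 in DOHH-2. Germinal centre genes were lower in WSU-DLCL2 in 4 of 24 and higher in 0 (4 and 0 adjusted over the list alone, camera adjusted p = 0.0373; adjusted p = 0.877 with an estimated correlation), and B cell receptor genes in 3 of 23 and 0 (5 and 1 adjusted over the list alone, camera adjusted p = 0.0123; adjusted p = 0.788 with an estimated correlation). INSIG1, a brake on sterol synthesis, differed by 1.78 ± 0.24 and FASN by 1.43 ± 0.30. None of 35 MYC targets of ribosome biogenesis differed between lines by edgeR (adjusted over the list alone also 0, camera adjusted p = 0.676). SMAD1, at 0 control counts in WSU-DLCL2, was at least 63.4-fold higher at 50 nM there, and ATP6V0A1, at 0 control counts in DOHH-2, was at least 74.5-fold higher at 20 nM there. In all 970 genes differed, 551 with the higher effect in WSU-DLCL2 and 419 with the lower. The count was 288 without the WSU-DLCL2 12 h set, 586 without the DOHH-2 12 h set and 609 among genes of at least 5 CPM.

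Between times the high-dose effect differed for 162 genes, 96 with a larger value at 12 h than at 6 h and 66 with a smaller one. The high-dose effect on DHRS2 was larger at 12 h by a log2 difference of 3.76 ± 0.45, and that on the nuclear RNA NEAT1 by 1.91 ± 0.20. The effect was smaller at 12 h for the heat shock gene HSPA1B (-1.71 ± 0.34), MPV17L2 (-1.62 ± 0.26) and CCNE1 (cyclin E, -1.47 ± 0.27). Part of the DHRS2 difference lies in the controls. From 6 h to 12 h these went from 0.943 to 0.234 CPM in WSU-DLCL2 and from 0.731 to 0.191 CPM in DOHH-2. At the higher dose DHRS2 went from 11.4 to 53.3 CPM in WSU-DLCL2 and from 16.8 to 40.1 CPM in DOHH-2. NEAT1 in WSU-DLCL2 stood at 124 CPM at 50 nM at 6 h and 624 CPM at 12 h. The high-dose effect was lower at 12 h in 3 of 19 cholesterol synthesis genes and higher in 0 (10 and 0 adjusted over the list alone, camera adjusted p = 2.44e-06, or 0.513 with an estimated correlation). Of 28 DNA replication genes it was lower in 3 and higher in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 2.9e-06, or 0.513 with an estimated correlation). For NF-kB targets the effect was higher at 12 h in 1 of 21 and lower in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 0.00256, or 0.541 with an estimated correlation). The median of this list went from 0.23 at 6 h to 1.28 at 12 h in WSU-DLCL2, and from 0.66 to 0.61 in DOHH-2. The count depends on the method, with 343 genes by DESeq2, 1 by limma-voom, 2 among genes of at least 5 CPM, 102 with RLE size factors, 763 without a filter on low counts and 0 where edgeR fitted the dose effect as shared by both lines. At an unadjusted p under 0.05, 3051 genes passed. The direction depends on it too, since 74 genes were higher and 269 lower at 12 h by DESeq2 and 251 and 512 without a filter, against 181 and 38 under upper quartile factors and 58 and 57 without mitochondrial genes. Lower at 12 h were 0 genes by limma-voom, among genes of at least 5 CPM and in the shared fit. HSPA1B, MPV17L2 and CCNE1 thus did not pass under these 3 alternatives. DHRS2 and NEAT1 did not pass in the shared fit either, and at most 1 of them passed by limma-voom.

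The controls of the lines differed in 7282 genes, 3621 higher in WSU-DLCL2 and 3661 higher in DOHH-2. These p-values also rest on the spread of dose effects between times. A shift shared by all libraries of a set of line and time does not enter that spread. Chosen after the values were seen, the tumour suppressor gene CDKN2A was at 58.9 and 66.4 CPM in the WSU-DLCL2 controls and at 0 counts in both DOHH-2 controls, and the interleukin receptor gene IL7R at 0 counts in WSU-DLCL2 and at 30.2 and 32.5 CPM in DOHH-2. The count was 4470 among genes of at least 5 CPM and 4818 at 2-fold or more. Where the dose effect was fitted as shared by both lines it was 11262. That fit in effect sets all libraries of one line against all of the other, not the controls alone.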

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

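All tests of explanations in this part were chosen only after the results were seen. By tests of the difference itself, the high-dose effect differed between the lines for 970 genes and between 6 h and 12 h for 162 genes. The lists that differed between lines by camera, in favour of WSU-DLCL2, were the genes induced by deacetylase inhibitors (adjusted p = 0.00293, median difference 0.77), p53 targets (0.00293, 0.16), neuronal genes (0.0136), ATF4 and stress response genes (0.0171, 0.34) and FOXO targets (0.0196, 0.39). Those lower in WSU-DLCL2 were B cell receptor signalling (0.0123, -0.45), interferon response (0.0136, -1.05), cytosolic ribosomal proteins (0.0136, -0.23, with 0 of 56 members past the threshold), MHC class II (0.0326, -0.49) and germinal centre identity (0.0373, -0.38). With an estimated correlation their adjusted p ran from 0.47 to 0.877. Some of these lists share members, so their results are not separate. CDKN1A is in the p53 list and in that of deacetylase inhibitors, and SESN1 in the p53 and FOXO lists.

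Between times, the lists with a lower high-dose effect at 12 h were MYC targets of ribosome biogenesis (camera adjusted p = 2.44e-06, median difference -0.37), MYC targets of metabolism (2.44e-06, -0.43), cholesterol synthesis (2.44e-06, -0.62), DNA replication (2.9e-06, -0.38), glycolysis (3.02e-04, -0.34) and cytosolic ribosomal proteins (0.00542, -0.15). Those with a higher effect at 12 h were NF-kB targets (0.00256, 0.60), interferon response (0.0106, 0.72), genes induced by deacetylase inhibitors (0.0229, 0.51), epithelial and stromal markers (0.0235) and neuronal genes (0.0281). With an estimated correlation their adjusted p ran from 0.513 to 0.97.

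Single genes named in the text that rose more or fell less in WSU-DLCL2 at the higher dose were, by the log2 difference, SLC17A7 at 5.53, CCND2 at 4.44, CDKN1A at 4.04, HRK at 3.79, DIRAS1 at 3.40, SLC16A3 at 3.21, BBC3 at 3.12, INSR at 2.86, NLRC5 at 2.02 and JUN at 2.01. Further ones were SESN1 at 1.98, MYCL at 1.90, PPP1R15A at 1.88, INSIG1 at 1.78, TNFRSF10B at 1.66, TP53INP1 at 1.63, TRIM47 at 1.501, FASN at 1.43 and SREBF1 at 1.23. Lower in WSU-DLCL2 were HLA-DQA1 at -1.22, TAP1 at -1.29, OAS1 at -1.67, KMO at -1.85, TNFAIP3 at -2.09, PTPN6 at -2.15, LMO2 at -2.51, HK1 at -2.64, PSMB9 at -2.85, DUSP5 at -3.09, EGR2 at -3.50, BANK1 at -3.72, IFIT3 at -3.82 and IFIT1 at -5.33. Between times, DHRS2 differed by 3.76, NEAT1 by 1.91, GLYATL1P3 by 1.85, ZMAT1 by 1.84, CLEC2D by 1.58, PTPN7 by 1.24 and BCL2 by 1.04, and CCNE1 by -1.47, RRP9 by -1.48, CD3EAP by -1.49, MPV17L2 by -1.62 and HSPA1B by -1.71. Over all genes, limma-voom called 1 difference between times and the filter of 5 CPM called 2, all of them rises. With a dose effect shared by both lines 0 were called. None of the listed falls thus passed under these alternatives. Of the listed rises at most 1 passed by limma-voom, at most 2 among genes of at least 5 CPM and 0 in the shared fit. Genes with 3 or fewer control counts in a line are not listed here.

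Genes at or near 0 in the controls rose at the higher dose: of the tested genes with 3 or fewer control counts, 858 of 1608 rose and 0 fell in WSU-DLCL2, and 615 of 1623 rose and 0 fell in DOHH-2, a fall from so few counts being out of reach. These genes were tested because other libraries held counts of them, which favours genes that rise, so the shares are those of a selected set. Of all genes at 0 in both controls of a line, 86.3% to 92.6% stayed at 0 in a higher-dose library. An even background such as genomic DNA is argued against, since at most 1.35% of the genes at 0 in both controls of a line reached 10 counts in a higher-dose library. RNA of the other line is argued against, since the rising genes reached a median of 124% of their level in the other line in WSU-DLCL2 and 77.7% in DOHH-2. RNA of the other line would bring every gene to the same share. Of genes at 0 in the controls of the line and at a mean of at least 50 CPM, by library totals, in those of the other, 2 and 6 were found, and these reached 0.04% and 0.0938% of their level there. SMAD1, which lay below that bound of 50 CPM in DOHH-2, reached 2.81 and 3.12 CPM at 50 nM in WSU-DLCL2 against 29.5 and 32.0 CPM in the DOHH-2 controls. RNA of epithelial or stromal cells is argued against as well, since EPCAM, CDH1, KRT19, COL1A2 and COL3A1 together had 5 counts in the 4 higher-dose libraries against 1012 for COL1A1. Opening of silent genes by inhibition of deacetylases may account for the rise, but no biological explanation was tested.

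Interferon response genes rose more in DOHH-2 than in WSU-DLCL2, with a median difference of -1.05 over 20 genes (camera adjusted p = 0.0136, fry adjusted p = 0.172). The list had adjusted p = 0.788 with an estimated correlation, and 5 of its 20 members passed. Unequal doses may account for it. With WSU-DLCL2 at 5 nM set against DOHH-2 at 20 nM the median was -0.53 (camera adjusted p = 0.109, fry adjusted p = 0.602), and against DOHH-2 at 2 nM it was -0.12 (camera adjusted p = 0.517). A p above the threshold does not show that the values were equal, and no dose was given to both lines. The adjustment over all lists was chosen after the unadjusted values had been seen, of which that for 5 nM against 20 nM by camera was under 0.05. A higher starting level in WSU-DLCL2 is neither shown nor excluded, as 8 of the 20 genes started higher there and 6 lower. The rank correlation of start and difference over genes was -0.334 (permutation p = 0.152, two-sided). The same controls enter both values with opposite signs, so their noise alone pulls it below 0, and it cannot decide the question. A single set of libraries cannot be told apart from the lines, since the median moved to -0.446 without the DOHH-2 12 h set, nearest to 0 of the 4. A difference between the lines themselves stays open and was not tested apart from the dose.

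Genes highest at the lower dose were shared by the lines, 71 genes against 5.68 if the lines were independent. The overlap exceeded that of independent lists (one-sided Fisher's exact p = 7.74e-59, over genes that are not independent). The rise at the lower dose was itself shared, with 1319 genes higher in both lines against 413 if the lines were independent. Part of the overlap follows from that, so the overlap does not test the fall at the higher dose and does not exclude noise of the lower-dose libraries. The scaling factors are argued against by the lowest count under 3 other scalings, 62 genes. A wrong label of a lower-dose library is argued against by the genes peaking 2-fold in 1 set. At least 87.9% of them were highest at the lower dose at the other time of the line, against 23.7% to 31.9% of all genes. For these genes the values also argue against noise of a single lower-dose library. They do not test a shift shared by the lower-dose libraries. A response of these genes that turns with dose is a candidate explanation, as a hypothesis found and tested on the same data. No biological explanation was tested, since the design holds 1 dose on either side.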

How the results depend on the processing

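The alternatives with upper quartile factors and without mitochondrial genes were chosen after the results were seen, and all others before. Over 13 counts, 102 alternative values stayed within 1.5 times the reported one and 37 did not. With a mean of at least 5 CPM, where fewer genes are tested, the counts were 4946 at 50 nM and 2203 at 5 nM in WSU-DLCL2, 1220 at 2 nM in DOHH-2, 6161 over both lines. Between lines there were 609 genes, 2 between times and 4470 between controls. At an absolute log2 fold change of at least 1, which can only remove genes, they were 4858 at 50 nM, 3283 at 5 nM and 1809 between doses in WSU-DLCL2. In DOHH-2 they were 3826 at 20 nM, 1632 at 2 nM and 1458 between doses, with 4505 over both lines and 4818 between controls. The difference between times gave 102 genes with RLE factors, 343 with DESeq2, 1 with limma-voom, 763 without a filter and 0 with a dose effect shared by both lines. The cause was not tested. The shared fit gave 11262 genes for the comparison of controls, where it in effect compares all libraries of the 2 lines. Leaving out each set of line and time in turn gave 3741 to 8256 genes at 50 nM, 1804 to 5649 at 5 nM and 0 to 3906 between doses in WSU-DLCL2. For DOHH-2 it gave 4086 to 6173 at 20 nM, 657 to 2056 at 2 nM and 656 to 2508 between doses. Between lines it gave 288 to 909 between lines, with fewer libraries in each fit. A lone set of a line is then assumed to vary like the other line. Of the gene lists, 11 passed at 50 nM in WSU-DLCL2 and 12 at 20 nM in DOHH-2 with the preset correlation, 0 and 0 with an estimated one, and 7 to 12 and 8 to 12 with a set left out. Lists called higher went from 4 to 1 at 20 nM without the DOHH-2 12 h set and from 4 to 2 at 50 nM without the WSU-DLCL2 12 h set. MYC was below its control in 8 of 8 pairs with either prior count. For 164 named genes, 4218 of 4413 alternative values kept their direction and side of the threshold, 138 were no longer past it, 56 passed it newly and 1 reversed. That one was GLYATL1P3 at 20 nM in DOHH-2, which was -1.45 without the DOHH-2 12 h set and 1.19 without the 6 h set. Each value is that of the remaining time. The level went from 14.6 CPM in the control to 5.37 CPM at 20 nM at 6 h, and from 14.8 to 34.4 CPM at 12 h. Not run were the pseudocount alternatives, since the file holds counts, leaving out sets for the difference between times, which leaves no residual degrees of freedom, and single-line fits for results over both lines. Totals of 27574463 to 36682390 counts limit genes near 0, for which lower bounds or counting intervals are given, and the single library per condition leaves the spread between repeats of a condition unmeasured.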

Other observations

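Among the results in this part, the list tests and the count over splits of the libraries were chosen before the results were seen. Metabolic genes moved in part at 50 nM in WSU-DLCL2. Of 21 glycolysis genes 10 fell and 3 rose (12 and 3 adjusted over the list alone, camera adjusted p = 0.0489; adjusted p = 0.76 with an estimated correlation). Hexokinase HK2 was at -1.31 ± 0.24, PFKP at -1.22 ± 0.17 and the lactate exporter SLC16A3 at 3.25 ± 0.23. Without the WSU-DLCL2 12 h set the list did not pass (camera adjusted p = 0.327). In DOHH-2 at 20 nM 8 of 21 fell and 4 rose (12 and 4 adjusted over the list alone, camera adjusted p = 0.057, and 0.00308 without the DOHH-2 6 h set), and hexokinase HK1 rose by 2.45 ± 0.19 while HK2 fell by 1.45 ± 0.24. Of 19 cholesterol synthesis genes 6 rose and 2 fell in WSU-DLCL2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.977). INSIG1 was at 1.54 ± 0.17 and ACAT2 at -0.87 ± 0.15. The median of this list was -0.09 and its mean 0.14, so they differ in sign. Of 9 fatty acid synthesis genes 4 fell and 2 rose in WSU-DLCL2 (5 and 2 adjusted over the list alone, camera adjusted p = 0.174). ELOVL6 was at -1.84 ± 0.19 and SREBF1 at 1.24 ± 0.22. ATF4 and stress response genes rose in 4 of 19 and fell in 6 in WSU-DLCL2 (4 and 6 adjusted over the list alone, camera adjusted p = 0.28). PPP1R15A was at 1.81 ± 0.22 and ATF5 at -1.70 ± 0.17.

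Single genes of cytokine signalling and of the cell cycle changed, while their lists did not pass by camera. Of 10 STAT targets 4 rose and 1 fell at 50 nM in WSU-DLCL2 (4 and 1 adjusted over the list alone, camera adjusted p = 0.492), and 6 rose and 2 fell at 20 nM in DOHH-2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.324). STAT3 was at 1.66 ± 0.18 in WSU-DLCL2 and 1.46 ± 0.18 in DOHH-2, and the kinase gene PIM1 at 1.64 ± 0.21 and 1.06 ± 0.20. Of 9 cell cycle inhibitors 3 rose and 2 fell in WSU-DLCL2 (3 and 2 adjusted over the list alone, camera adjusted p = 0.74), and 2 rose and 1 fell in DOHH-2 (2 and 1 adjusted over the list alone, camera adjusted p = 0.769). CDKN2D was at 1.78 ± 0.22 in WSU-DLCL2 and 1.71 ± 0.23 in DOHH-2. Of 21 NF-kB targets 10 rose and 5 fell in WSU-DLCL2 (10 and 5 adjusted over the list alone, camera adjusted p = 0.425). IER3 was at 4.81 ± 0.46 and LTA at -2.40 ± 0.28. MHC class I genes rose in 5 of 14 and fell in 4 in WSU-DLCL2 (6 and 4 adjusted over the list alone, camera adjusted p = 0.719). NLRC5, an activator of these genes, was at 1.78 ± 0.20 and PSMB10 at -1.61 ± 0.26.

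For the high dose against the control over both lines, 7344 genes passed in the 8 libraries with line and time as blocks. The libraries are paired by line and time, and 8 splits part every pair of control and treated libraries. Of these only the real one gave as many genes, with 0 as the highest of the other 7. A total of 8 splits is too few for a share under 0.05. The other 7 reverse control and treated libraries in some pairs, which leaves the drug effect in their residual spread. A further 24 splits part 2 pairs and leave it there too, with 3 genes at most. Low counts were thus built into all of these splits, which do not measure what arises without a drug effect.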
